A study of Rattus norvegicus with 48 samples.

How the data were processed

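Total RNA from kidneys of male rats, aged 12 weeks in the sample labels, was hybridised to whole-transcript arrays. Per the labels' protocols, rats of 4 strains (F, L, FL and LF) received 100 mg per kg body weight per day of indole-3-carbinol by gavage for 7 or 10 days, or vegetable oil carrier, with 8 rats per group. The series design gives 4 biological replicates for each of the 12 groups, which makes 48 arrays. Whether an array holds RNA of 1 rat or a pool is not stated in the labels. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and column purified, ribosomal RNA was removed from 1 µg, and biotin-labelled sense targets were made. The submitters' processing notes name RMA and limma without versions or roles. The deposited values are log2 signals which, per the labels' naming of RMA, the authors made by background correction, quantile normalization and summary of probes into 1 value per probe set. Values between 1.04 and 14.02, array medians of 5.66 to 6.06 and 2 decimals in the deposited table were checked against a log2 scale. The medians differ between arrays, so the deposited probe sets alone do not show the equal distributions that quantile normalization gives. Which probe sets were kept, and with which probe annotation, is not stated in the labels.

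The table held 8797 probe sets with 0 missing values and 0 unmapped columns, and each column was assigned to strain, day and replicate from its label. Of the probe sets, 7603 carried 1 gene symbol in the annotation, 409 several and 785 none. Names rested on the Entrez identifier where it matched the rat reference annotation (7584 probe sets), and 7589 genes could be named. For the 14 symbols with several probe sets, the probe set with the highest mean over all arrays was used. Array quality was read from the SD over probe sets of each array, called the array spread (2.29 to 2.54), and from correlations within groups (0.979 to 0.992). The first principal component held 24.4% of the variance and ran with the array spread, the next ones 9.02% and 5.34%. The array spread averaged 2.48, 2.46, 2.43 and 2.38 over the 12 arrays of replicate numbers 1, 2, 3 and 4.

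Analyses were run in R 4.3.3 with limma 3.58.1. One mean per group was fitted to all 48 arrays (36 residual and 3.69 prior degrees of freedom), and 24 contrasts and 1 moderated F test with 6 numerator degrees of freedom were read from that fit, each adjusted over all probe sets by Benjamini and Hochberg at a threshold of 0.05. The contrasts were each treated day against day 0 per strain and in the mean of the strains, day 10 against day 7 in that mean, the 6 strain pairs at day 0, and the differences between strains in the day 10 response, plus F against L at day 7. Intervals are 95% intervals from the same fit for the single gene. The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

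Genes were named by a rule: the 10 largest rises and 10 largest falls past the threshold in the mean of the strains at day 7 and at day 10, the 5 largest in each direction elsewhere, up to 4 members of each list described with the smallest p, the 10 smallest p of the F test, and Cyp1a1, Ace, Agt, Agtr1a, Havcr1 and Lcn2 throughout. Spp1 was on that last list and had no named probe set. The clock genes, the neighbours of Ace and probe set 7105149 were added after the values were seen.

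Gene lists were tested with camera of limma at a preset correlation of 0.01 and adjusted over the 26 lists within a contrast. There were 14 pathway lists (AhR and Nrf2 targets, angiotensin and kallikrein system, tubular injury markers, matrix and fibrosis, chemokines and cytokines, interferon response, complement and coagulation, histocompatibility complex, cell cycle, p53 and stress, fatty acid oxidation, cholesterol synthesis, hypoxia, vasoactive and natriuretic response) and 12 cell type or tissue lists (proximal tubule, loop and distal convoluted tubule, collecting duct, podocyte, endothelium, smooth muscle with pericyte and fibroblast, macrophage, T and natural killer cell, B and plasma cell, granulocyte and mast cell, erythroid cell and platelet, adipose and adrenal tissue). Of 696 list genes, 439 were measured. Each set test was repeated with an estimated correlation, with fry (directional p), with the block and with the mean over a gene's probe sets.

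The scripts were tested on simulated data made from the residuals of the arrays with 200 changed probe sets. In the strain mean at day 7, 92.5% of changes of 0.5 log2 and 100% of changes of 1 or 2 were called. In LF at day 10 the shares were 47.8%, 91.0% and 98.5%, and in the LF against L response 14.9%, 71.6% and 97.0%, with at most 5 unchanged probe sets called. In 100 draws with no change, probe sets were called in 6 draws for the strain mean at day 7 (up to 231) and in 4 for LF at day 10 (up to 915). In the same draws camera with the preset correlation called at least 1 list in 85 draws for the strain mean at day 7 and in 72 for LF at day 10, against 2 and 6 with an estimated correlation, so calls at the preset correlation are liberal for these arrays.

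Pairing was checked once. The array file names in the labels group the 12 arrays of a replicate number into a run, so the number was also fitted as a block. After removal of group means, arrays of the same number correlated at a mean of 0.0942 and other arrays at -0.0314. For 26 of 48 arrays the mean correlation with arrays of other groups was highest for their own number. LF at day 7 against day 0 was the 1 contrast within strains or between strains at day 0 in which all 4 pairs lay above 0.1 (0.128 to 0.212). Blocked values stand beside a result where they change a call or move a count by over 1.5 times.

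Alternatives fixed beforehand were the block, leaving out the dimmest 0.25 of probe sets, a second quantile normalization, subtraction of array medians, a trended and robust variance model, array weights, a fit on the arrays of the comparison alone, and leaving out each array or each replicate number. Alternatives added after seeing the data were the array spread as a covariate, leaving out the 5 arrays of lowest spread, and single arrays left out of the contrasts of the strain mean. Splits of the same arrays into other groups were fitted in the same way. Probe-level values were not analysed here.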

Results

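Kidney RNA from male rats of 4 strains, which the labels name F, L, FL and LF without saying what the letters stand for, was profiled on whole-transcript arrays. Rats of each strain received indole-3-carbinol by gavage for 7 or 10 days at 100 mg per kg body weight per day, or the vegetable oil carrier. The carrier kidneys are called day 0, as in the labels. Indole-3-carbinol is a plant compound whose products activate the aryl hydrocarbon receptor, which switches on Cyp1a1. Each of the 12 groups had 4 arrays, 48 in all, with 8 rats per group in the treatment protocol, and the labels do not say whether an array holds 1 rat or a pool. Values were log2 array signals for 8797 probe sets, of which 7603 carried 1 gene symbol. Genes called largest, highest or lowest are ranked among probe sets with 1 gene symbol, and other probe sets can lie beyond them. Array medians lay between 5.66 and 6.06, and the number of arrays limits the precision. Each change is a log2 difference ± its standard error from limma, with 4 arrays in each group, and the threshold is an adjusted p of 0.05. Replicate numbers name array runs of 12 arrays, and a value with the block is one with the run in the model.

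After 7 days, averaged over the 4 strains, Havcr1, Hmox1 and Cyp1a1 rose in the kidney, and the interferon-induced Oas1a, Mx1 and Mx2 and the distal nephron genes Calb1 and Slc8a1 fell. Havcr1, the kidney injury molecule shed by damaged proximal tubules, rose by 1.77 ± 0.27 (adjusted p = 3.40e-05), Hmox1, the haem-degrading stress enzyme, by 1.73 ± 0.43 (adjusted p = 0.0119), and Cyp1a1 by 1.33 ± 0.22 (adjusted p = 8.83e-05). Hmox1 arrays at day 7 lay at 4.40 to 5.17 in L and 4.99 to 5.55 in FL, close to day 0 (4.74 to 5.35 and 4.99 to 5.14). They ranged from 5.75 to 9.71 in F and from 5.87 to 10.57 in LF, so the mean rise came from F and LF. The other large rises were Serpina3n (0.91 ± 0.17), Fga (0.69 ± 0.15), Lum (0.65 ± 0.11), Sult1a1 (0.76 ± 0.16), Pdk4 (0.70 ± 0.16), Angptl4 (0.67 ± 0.13) and Slc25a25 (0.75 ± 0.20), each at an adjusted p of at most 0.0172. The largest falls among named genes were Cbx3 (-1.48 ± 0.43), Oas1a (-1.39 ± 0.27), Cxcl13 (-1.17 ± 0.18), Mx2 (-1.12 ± 0.16), Grem1 (-0.99 ± 0.14), Mx1 (-0.97 ± 0.15), Slfn4 (-0.96 ± 0.16), Oasl2 (-0.93 ± 0.12), Nr1d1 (-0.90 ± 0.13) and Slc8a1 (-0.90 ± 0.13), each at an adjusted p of at most 0.0354. Probe set 7105149, which has no gene name, fell further (-1.93 ± 0.083). Oas1a, Mx1, Mx2 and Oasl2 are antiviral genes switched on by interferon, and Cxcl13 is a chemokine that attracts B cells. Agtr1a, the main angiotensin II receptor, fell by 0.50 ± 0.10 (adjusted p = 0.00191) and Lcn2, a secreted marker of tubular damage, rose by 0.35 ± 0.10 (adjusted p = 0.0365). Ace, the angiotensin converting enzyme, stood at -0.24 ± 0.079 (adjusted p = 0.0619) and Agt, the angiotensin precursor, at 0.0019 ± 0.071 (adjusted p = 0.991), neither past the threshold. Ace passed it with the block (adjusted p = 0.023), array weights (0.0282) and the dimmest probe sets left out (0.0477). Cbx3 lost its call with the array spread as covariate (adjusted p = 0.11), and Cbx3 and Lcn2 lost theirs without the 5 arrays of lowest spread (adjusted p = 0.0611 and 0.0566).

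Among the injury markers, 10 of 22 measured members rose and 0 fell (11 and 2 adjusted over the list alone), with Havcr1, Tnfrsf12a (0.43 ± 0.078), Fgb (0.58 ± 0.11) and Timp1 (0.50 ± 0.099) leading. Camera on the list gave adjusted p = 8.34e-10, and adjusted p = 0.197 with an estimated correlation. Of the interferon response genes, 0 of 21 measured members rose and 12 fell (0 and 17 adjusted over the list alone), among them Gbp2 (-0.56 ± 0.099) beside the Mx genes and Oas1a. The set test gave adjusted p = 3.88e-12, and adjusted p = 0.197 with an estimated correlation. The white blood cell markers Adgre1, Aif1 and Cd4 also fell past the threshold in this comparison. Adgre1 lost its call with the array spread as covariate (adjusted p = 0.0663), Aif1 with array medians subtracted (0.0577) and Cd4 after a second quantile normalization (0.0618). Counts for the white blood cell lists are not given for this comparison. Of the loop of Henle and distal convoluted tubule markers, 0 of 18 measured members rose and 7 fell (1 and 9 adjusted over the list alone), among them Calb1 (-0.89 ± 0.12), Slc8a1 (-0.90 ± 0.13), Slc12a1 (-0.25 ± 0.056) and Kcnj1 (-0.25 ± 0.057), which encode calcium binding and ion transport proteins. As a set it had adjusted p = 5.24e-06, and adjusted p = 0.421 with an estimated correlation. Of the collecting duct markers, 0 of 18 measured members rose and 8 fell (2 and 9 adjusted over the list alone), including Slc14a2 (-0.55 ± 0.06), Aqp2 (-0.52 ± 0.082), Aqp4 (-0.53 ± 0.10) and Scnn1g (-0.35 ± 0.079), which carry urea, water and sodium. By camera this was adjusted p = 0.00917, and adjusted p = 0.614 with an estimated correlation. Falls past the threshold were not limited to these segments. The proximal tubule markers Slc5a2 and Lrp2, the podocyte marker Podxl and the endothelial marker Plvap also fell, and each lost its call under some alternative. In the angiotensin and kallikrein list 0 of 13 measured members rose and 4 fell (0 and 6 adjusted over the list alone), the falls being Agtr1a (-0.50 ± 0.10), Nr3c2 (-0.31 ± 0.071), Mme (-0.24 ± 0.067) and Anpep (-0.23 ± 0.068). For the whole list camera gave adjusted p = 0.0305, and adjusted p = 0.421 with an estimated correlation. Of the AhR and Nrf2 targets, 2 of 15 measured members rose and 1 fell (2 and 2 adjusted over the list alone). Cyp1a1 and Hmox1 were the rises and Gclc the fall (-0.14 ± 0.042). The set test of this list gave adjusted p = 0.0373, adjusted p = 0.421 with an estimated correlation, and adjusted p = 0.0554 with the block. Of the chemokine and cytokine genes, 1 of 27 measured members rose and 6 fell (1 and 11 adjusted over the list alone), with Cxcl12 (-0.72 ± 0.075), Cxcl13 (-1.17 ± 0.18) and Cxcl9 (-0.37 ± 0.075) falling and Ccl21 (0.32 ± 0.081) rising. Its set test gave adjusted p = 0.0378, adjusted p = 0.421 with an estimated correlation and adjusted p = 0.104 with the block. Anpep and Gclc lost their calls with array medians subtracted (adjusted p = 0.0628 and 0.115), and Anpep after a second quantile normalization (adjusted p = 0.0734). Mme, Anpep and Gclc lost them with the array spread as covariate (adjusted p = 0.0804, 0.111 and 0.0928) and without the 5 arrays of lowest spread (0.0837, 0.0784 and 0.139).

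In all, 105 probe sets rose and 330 fell from day 0 to day 7 in the mean of the strains. With the block, the counts were 189 higher and 787 lower, after a second quantile normalization 267 higher and 367 lower, and with array medians subtracted 256 higher and 310 lower. The excess of falls over rises thus depended on the scaling, and array signals were spread more narrowly on day 7 arrays (mean SD over probe sets 2.41 ± 0.0543, SD, n = 16) than on day 0 arrays (2.45 ± 0.051, SD, n = 16). Leaving out single arrays gave totals between 284 (without LF day 0 replicate 2), with 289 without F day 7 replicate 4, and 720 (without L day 0 replicate 4).

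After 10 days, in the mean of the strains, Havcr1 and other markers of tubular injury rose again, and Calb1, Slc8a1 and Aqp2 of the distal nephron and collecting duct again fell. Havcr1 rose by 2.87 ± 0.27 (adjusted p = 1.74e-09), a 7.32-fold higher signal, Hmox1 by 1.88 ± 0.43 (adjusted p = 0.0079), Cyp1a1 by 1.74 ± 0.22 (adjusted p = 9.14e-07) and Lcn2 by 0.75 ± 0.10 (adjusted p = 3.84e-06). Hmox1 did not rise evenly. Its arrays at day 10 ranged from 5.74 to 9.09 in F, 5.10 to 8.64 in L and 4.68 to 9.59 in FL. In LF they ranged from 5.22 to 6.10, beside 5.87 to 10.57 at day 7. The remaining large rises were Serpina3n (1.13 ± 0.17), Clu (1.01 ± 0.11), Slc25a25 (0.98 ± 0.20), Fga (0.92 ± 0.15), Fgb (0.92 ± 0.11), Cdkn1a (0.87 ± 0.15) and Rasd1 (0.85 ± 0.15), each at an adjusted p of at most 0.00163. Clu encodes the secreted chaperone clusterin, Fga and Fgb fibrinogen chains, and Cdkn1a the cell cycle inhibitor p21. The largest falls among named genes were Scd (-1.04 ± 0.27), Nr1d1 (-0.85 ± 0.13), Calb1 (-0.84 ± 0.12), Dbp (-0.78 ± 0.10), Slc8a1 (-0.76 ± 0.13), Grem1 (-0.75 ± 0.14), Cxcl13 (-0.71 ± 0.18), Scd2 (-0.70 ± 0.15), Mcoln3 (-0.67 ± 0.10) and Cxcl12 (-0.64 ± 0.075), each at an adjusted p of at most 0.0237. Probe set 7105149 again fell further (-1.76 ± 0.083). Scd and Scd2 are fatty acid desaturases, and Nr1d1 and Dbp are transcription factors of the daily clock. Ace fell by 0.29 ± 0.079 (adjusted p = 0.034), while Agtr1a at -0.25 ± 0.10 (adjusted p = 0.326) and Agt at -0.027 ± 0.071 (adjusted p = 0.995) did not pass the threshold. Agtr1a passed it after a second quantile normalization (adjusted p = 0.042) and with the array spread as covariate (0.0244), and Ace and Cxcl13 lost their calls without the 5 arrays of lowest spread (adjusted p = 0.103 and 0.0666). Ace arrays at day 10 lay below all day 0 arrays in F (6.45 to 7.34 against 7.49 to 7.68) and in LF (6.70 to 6.98 against 7.05 to 7.40). They overlapped day 0 in L (5.71 to 6.12 against 5.78 to 6.27) and in FL (5.77 to 6.64 against 6.06 to 6.48), so the mean fall came mainly from F and LF. At day 7 the Ace ranges were 6.95 to 7.48 in F, 6.45 to 6.80 in LF, 5.73 to 6.22 in L and 5.99 to 6.38 in FL.

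Of the injury markers, 12 of 22 measured members rose and 1 fell (16 and 1 adjusted over the list alone). Tested together the members had adjusted p = 4.12e-32, and adjusted p = 0.00116 with an estimated correlation. After Havcr1 the smallest p-values among them belonged to Clu, Timp1 (0.83 ± 0.099) and Fgb. In the p53 and stress list 6 of 20 measured members rose and 0 fell (8 and 1 adjusted over the list alone), with Cdkn1a (0.87 ± 0.15), Hspb1 (0.35 ± 0.067), Gadd45a (0.23 ± 0.055) and Jun (0.37 ± 0.087). Camera on the list gave adjusted p = 3.47e-07, and adjusted p = 0.127 with an estimated correlation. In the fatty acid oxidation list 5 of 28 measured members rose and 0 fell (11 and 1 adjusted over the list alone), with Ehhadh (0.39 ± 0.071), Pdk4 (0.78 ± 0.16), Acadl (0.26 ± 0.068) and Ech1 (0.28 ± 0.08). The set test gave adjusted p = 7.09e-07, and adjusted p = 0.378 with an estimated correlation. Of the smooth muscle, pericyte and fibroblast markers, 4 of 15 measured members rose and 0 fell (5 and 1 adjusted over the list alone), namely Tagln (0.59 ± 0.075), Lum (0.68 ± 0.11), Cspg4 (0.21 ± 0.054) and Des (0.31 ± 0.082). As a set it had adjusted p = 0.0014, and adjusted p = 0.176 with an estimated correlation. In the loop and distal convoluted tubule list 1 of 18 measured members rose and 4 fell (1 and 8 adjusted over the list alone), led by Calb1, Slc8a1, Kcnj1 (-0.25 ± 0.057) and Slc12a1 (-0.20 ± 0.056). By camera this was adjusted p = 6.53e-08, and adjusted p = 0.176 with an estimated correlation. In the collecting duct list 1 of 18 measured members rose and 5 fell (2 and 7 adjusted over the list alone), with Slc14a2 (-0.48 ± 0.06), Aqp2 (-0.61 ± 0.082) and Fxyd4 (-0.32 ± 0.083) falling and Scnn1a (0.32 ± 0.078) rising. For the whole list camera gave adjusted p = 0.00108, and adjusted p = 0.532 with an estimated correlation. Of the 21 interferon response genes none passed the threshold at day 10 (camera adjusted p = 0.37). Slc12a1 and Fxyd4 lost their calls without the 5 arrays of lowest spread (adjusted p = 0.0828 and 0.0523).

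The day 10 counts were 111 probe sets higher and 101 lower than day 0, and 206 higher and 201 lower after a second quantile normalization. Between day 10 and day 7, 8 probe sets were higher and 2 lower. Cbx3 (2.32 ± 0.43, adjusted p = 0.00993) and the interferon-inducible genes Mx2 (0.89 ± 0.16), Slfn4 (0.74 ± 0.16), Mx1 (0.71 ± 0.15) and Oasl2 (0.54 ± 0.12), led the rises, and Or6b2b (-0.72 ± 0.14) and Atp1b4 (-0.19 ± 0.038) were the falls. Havcr1 stood at 1.10 ± 0.27 between the days (adjusted p = 0.103). Of the interferon genes, 2 of 21 measured members rose and 0 fell (16 and 0 adjusted over the list alone) between the days. Tested together the members had adjusted p = 7.14e-15, and adjusted p = 0.215 with an estimated correlation. The list mean per array, centred on all arrays, went from -0.45 at day 7 to 0.63 at day 10 in LF, from -0.20 to 0.048 in L, from -0.16 to -0.075 in FL and from -0.19 to -0.22 in F. Of the injury markers, 1 of 22 measured members rose and 0 fell (12 and 0 adjusted over the list alone), and the rise was Clu (0.52 ± 0.11). By camera this was adjusted p = 1.07e-06, and adjusted p = 0.612 with an estimated correlation. With the block, 17 higher and 4 lower probe sets differed between day 10 and day 7, and of 14 single arrays that moved the count by over 1.5 times FL day 10 replicate 4 moved it most, to 64 probe sets. Mx1, Slfn4, Oasl2 and Clu lost their calls with the array spread as covariate (adjusted p = 0.172, 0.192, 0.172 and 0.114), where 3 probe sets were higher and 2 lower. Mx1, Slfn4 and Oasl2 lost them with array medians subtracted (adjusted p = 0.0611, 0.0611 and 0.0542), Slfn4 and Oasl2 after a second quantile normalization (0.0819 and 0.0572), and Mx1 and Clu without the 5 arrays of lowest spread (0.0553 and 0.0553). Without any one replicate number at most 2 probe sets passed.

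A probe set without a gene name in the annotation, singled out after its values were seen, fell in every strain at both days. Probe set 7105149 fell by 1.93 ± 0.083 at day 7 and by 1.76 ± 0.083 at day 10 in the mean of the strains (adjusted p = 1.02e-20 and 2.68e-19), the smallest adjusted p of all probe sets in both comparisons. Within strains probe set 7105149 ranged from -2.10 ± 0.17 in FL at day 7 to -1.52 ± 0.17 in LF at day 10.

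**Figure D1:**
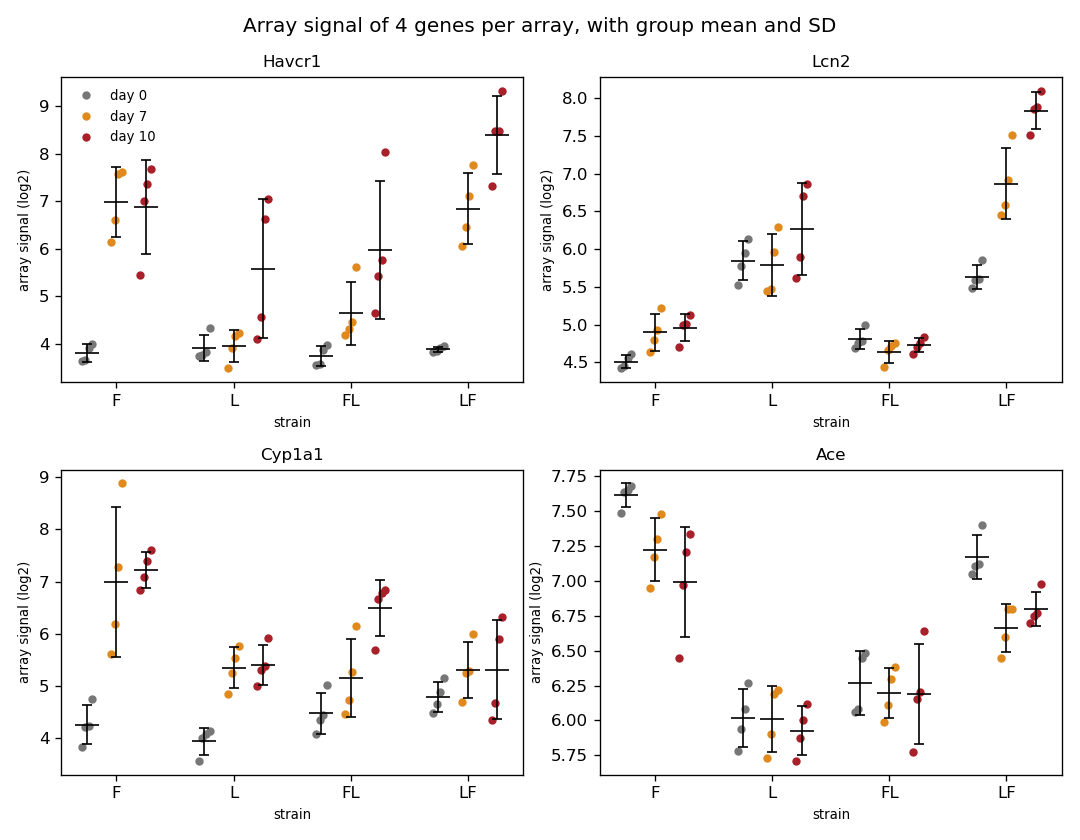
Array signal (log2) of Havcr1, Lcn2, Cyp1a1 and Ace on each array by strain, with points coloured by day and black bars for the group mean ± SD of 4 arrays. Havcr1 in LF moves from a mean of 3.88 at day 0 to 8.40 at day 10, and Ace at day 0 is highest in F at 7.62.

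The response within each strain was compared with that strain's own day 0 kidneys. In LF, Havcr1 rose by 2.96 ± 0.54 at day 7 and 4.52 ± 0.54 at day 10 (adjusted p = 0.000981 and 6.64e-07), from a group mean of 3.88 ± 0.056 to 8.40 ± 0.82 (SD, n = 4). Lcn2 rose by 1.24 ± 0.20 and 2.21 ± 0.20 (adjusted p = 0.000216 and 2.09e-09). For both genes all 4 LF arrays at day 7 and at day 10 lay above all 4 at day 0. Among named genes at day 7, Hmox1 (4.07 ± 0.86), Serpina3n (2.12 ± 0.35), Bmal1 (1.66 ± 0.29) and Sult1a1 (1.28 ± 0.32) were the other large rises, and Oas1a (-2.85 ± 0.54), Cxcl13 (-2.14 ± 0.35), Mx2 (-2.04 ± 0.31), Or10d5j (-2.01 ± 0.35) and Mx1 (-1.87 ± 0.31) fell most. Among named genes at day 10, the largest rises after Havcr1 were Serpina3n (2.21 ± 0.35), Lcn2 (2.21 ± 0.20), Clu (1.83 ± 0.21) and Slc34a2 (1.57 ± 0.22) and the largest falls Ces1e (-1.56 ± 0.22), Dbp (-1.43 ± 0.20), Or10d5j (-1.42 ± 0.35), Gadd45g (-1.42 ± 0.32) and Bhlhe41 (-1.21 ± 0.19). Of the injury markers, 11 of 22 measured members rose and 0 fell (14 and 0 adjusted over the list alone) at day 10. Camera on the list gave adjusted p = 4.60e-35, and adjusted p = 0.000608 with an estimated correlation. Of the interferon genes, 0 of 21 measured members rose and 10 fell (0 and 18 adjusted over the list alone) at day 7. The set test gave adjusted p = 3.78e-13, and adjusted p = 0.164 with an estimated correlation. Of the macrophage markers, 0 of 28 measured members rose and 5 fell (0 and 11 adjusted over the list alone) at day 7, among them Fcgr3a (-1.27 ± 0.27), Adgre1 (-0.93 ± 0.21), Aif1 (-0.55 ± 0.13) and Mpeg1 (-0.90 ± 0.21). As a set it had adjusted p = 0.00234, and adjusted p = 0.698 with an estimated correlation. Of the proximal tubule markers, 0 of 30 measured members rose and 4 fell (1 and 11 adjusted over the list alone) at day 7, among them the transporters Slc5a2 (-0.74 ± 0.14) and Slc34a3 (-0.62 ± 0.16). By camera this was adjusted p = 0.0162, and adjusted p = 0.788 with an estimated correlation. Aif1 lost its call with array medians subtracted (adjusted p = 0.0872) and Slc34a3 without the 5 arrays of lowest spread (0.0874). With each replicate number left out in turn, Lcn2 kept its call in 4 of 4 cases at day 7 and 4 at day 10, Havcr1 in 3 and 4, and Hmox1 at day 7 in 1. Cyp1a1 in LF stood at 0.51 ± 0.43 and 0.52 ± 0.43, short of the threshold (adjusted p = 0.539 and 0.999).

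The LF counts were 34 higher and 165 lower at day 7 and 52 higher and 26 lower at day 10. The block gave 89 higher and 633 lower at day 7, a second quantile normalization 187 higher and 207 lower at day 7 and 79 higher and 67 lower at day 10, and subtraction of array medians 133 higher and 174 lower and 76 higher and 74 lower. On the arrays of the comparison alone the LF counts were lower at both days, by over 1.5 times. So were those of F at day 10 and of FL at both days, as listed with the processing. Of 4 single arrays that moved the day 7 count by over 1.5 times LF day 0 replicate 2 moved it most, to 57 probe sets at day 7.

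In F, Havcr1 rose by 3.18 ± 0.54 at day 7 and 3.07 ± 0.54 at day 10 (adjusted p = 0.00128 and 0.00252), and Cyp1a1 by 2.73 ± 0.43 and 2.96 ± 0.43 (adjusted p = 0.000856 and 0.00015). For both genes all 4 treated F arrays at each day lay above all 4 at day 0. Among named genes at day 7, Slc25a25 (1.88 ± 0.39), Sult1a1 (1.33 ± 0.32) and Fgb (1.31 ± 0.23) were the next largest rises, and Scd2 (-1.50 ± 0.30), Nr1d1 (-1.47 ± 0.26), Calb1 (-1.35 ± 0.24), Or13a18 (-1.32 ± 0.29) and Slc8a1 (-1.30 ± 0.27) the largest falls. Among named genes at day 10, Obp1f (1.54 ± 0.32), Fgb (1.11 ± 0.23) and Clu (0.96 ± 0.21) followed among the rises, and Nr1d1 (-1.51 ± 0.26), Calb1 (-1.50 ± 0.24), Scd2 (-1.36 ± 0.30), Or13a18 (-1.28 ± 0.29) and Cacng5 (-1.10 ± 0.22) led the falls. Probe set 7197285, without a gene name, rose by 2.31 ± 0.39 at day 7 and 2.175 ± 0.39 at day 10, and probe set 7105149 fell by more than Scd2 and Nr1d1. Of the injury markers, 6 of 22 measured members rose and 0 fell (10 and 0 adjusted over the list alone) at day 7, including Timp1 (1.08 ± 0.20) and Gpnmb (0.91 ± 0.18). For the whole list camera gave adjusted p = 1.28e-17, and adjusted p = 0.0405 with an estimated correlation. At day 10, 3 of 22 measured members rose and 0 fell (7 and 0 adjusted over the list alone). Tested together the members had adjusted p = 1.77e-10, and adjusted p = 0.261 with an estimated correlation. In the collecting duct list 0 of 18 measured members rose and 3 fell (1 and 7 adjusted over the list alone) at day 7, with Slc14a2 (-0.68 ± 0.12), Aqp2 (-0.81 ± 0.16) and Aqp4 (-0.87 ± 0.21). Camera on the list gave adjusted p = 0.000116, and adjusted p = 0.283 with an estimated correlation. Lcn2 stood at 0.39 ± 0.20 and 0.45 ± 0.20, not past the threshold (adjusted p = 0.776 and 0.499), though the treated F arrays at each day also lay above day 0 for it. The F counts were 38 higher and 21 lower at day 7 and 7 higher and 14 lower at day 10. At day 7 they were 85 higher and 56 lower after a second quantile normalization, 62 higher and 40 lower with array medians subtracted, 87 higher and 62 lower with array weights and 109 higher and 74 lower with the array spread as covariate. At day 10 the block gave 15 higher and 27 lower, a second quantile normalization 45 higher and 37 lower and subtraction of array medians 29 higher and 33 lower. Without the 5 arrays of lowest spread Clu, Fgb, Scd2 and Cacng5 at day 10 lost their calls (adjusted p = 0.103, 0.0627, 0.13 and 0.0729), as did Clu with array weights (0.0541) and Or13a18 with medians subtracted (0.0516). With each replicate number left out in turn, Cyp1a1 kept its call in 4 of 4 cases at day 7 and 4 at day 10, and Havcr1 in 3 and 2. Of 5 single arrays that moved the count by over 1.5 times F day 0 replicate 4 moved it most, to 7, and the day 7 count to 37.

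In FL, Nupr1 and Asns fell at both days. Nupr1, a stress-induced chromatin protein, fell by 1.82 ± 0.21 at day 7 and 1.12 ± 0.21 at day 10 (adjusted p = 4.93e-07 and 0.0173), and Asns, asparagine synthetase, by 1.19 ± 0.18 and 0.83 ± 0.18 (adjusted p = 0.000153 and 0.0415). Dbp, Septin4 and P2rx4 fell at day 7 (-1.17 ± 0.20, -0.94 ± 0.17 and -0.91 ± 0.15) and Atf5 at day 10 (-0.58 ± 0.12). The rises were Rpl18-ps7 (1.18 ± 0.25) and Tagln (0.72 ± 0.15) at day 7 and Cyp1a1 (2.02 ± 0.43), Nfil3 (1.19 ± 0.23), Tnfrsf12a (0.72 ± 0.16) and Tagln (0.71 ± 0.15) at day 10. Havcr1 in FL stood at 0.90 ± 0.54 and 2.23 ± 0.54 (adjusted p = 0.812 and 0.119), Lcn2 at -0.17 ± 0.20 and -0.08 ± 0.20 (adjusted p = 0.912 and 0.999), and Cyp1a1 at day 7 at 0.68 ± 0.43 (adjusted p = 0.816). All 4 FL arrays nevertheless lay above all 4 at day 0 for Havcr1 at both days and for Cyp1a1 at day 10, and adjusted over its list alone Havcr1 had a p of 0.348 at day 7 and 0.00107 at day 10. Of the injury markers, 1 of 22 measured members rose and 0 fell (10 and 0 adjusted over the list alone) at day 10. The set test gave adjusted p = 2.75e-17, and adjusted p = 0.0444 with an estimated correlation. FL had 2 probe sets higher and 12 lower at day 7 and 4 higher and 4 lower at day 10, and 6 higher and 17 lower at day 7 with array medians subtracted. With the block Cyp1a1 and Tagln at day 10 lost their calls (adjusted p = 0.0519 and 0.0501), and Cyp1a1 kept its call in 0 of 4 cases with a replicate number left out. Asns and Atf5 at day 10 lost theirs with array weights (adjusted p = 0.0933 and 0.0814). Without the 5 arrays of lowest spread Nupr1, Asns and Atf5 at day 10 (adjusted p = 0.0649, 0.104 and 0.114) and Dbp and Septin4 at day 7 (0.0624 and 0.0789) lost theirs. Of 6 single arrays that moved the day 10 count by over 1.5 times, FL day 0 replicates 2 and 3 moved it most, to 1, and the day 7 count was 9 without FL day 0 replicate 1.

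In L, limma called 1 probe set at each day, probe set 7105149 (-1.64 ± 0.17 and -1.83 ± 0.17), against 353 and 378 probe sets at an unadjusted p under 0.05. Both of these numbers lie below 0.05 of the 8797 probe sets, the share expected with no change. With the block 2 probe sets passed at each day, and without L day 0 replicate 4 it was 3 at day 7. Havcr1 in L stood at 0.037 ± 0.54 at day 7 and 1.67 ± 0.54 at day 10 (adjusted p = 0.996 and 0.964), Cyp1a1 at 1.41 ± 0.43 and 1.45 ± 0.43 (adjusted p = 0.681 and 0.694), and Lcn2 at -0.052 ± 0.20 and 0.42 ± 0.20 (adjusted p = 0.994 and 0.999). All 4 L arrays at day 7 and at day 10 nevertheless lay above all 4 at day 0 for Cyp1a1, whose p adjusted over its list alone was 0.0369 and 0.0272, and for Havcr1 that p was 0.0413 at day 10.

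F and LF, which share no arrays, had calls in common. At day 7, 11 probe sets rose and 12 fell in both, where independent lists of those lengths would share 0.147 and 0.394. In addition 1 probe set rose in F and fell in LF. At day 10, 3 rose and 5 fell in both, against 0.0414 and 0.0414 for independent lists. Both strains were fitted together with 1 variance per probe set, so a probe set of low variance is called more easily in both. The numbers for independent lists are thus a rough baseline.

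**Figure D2:**
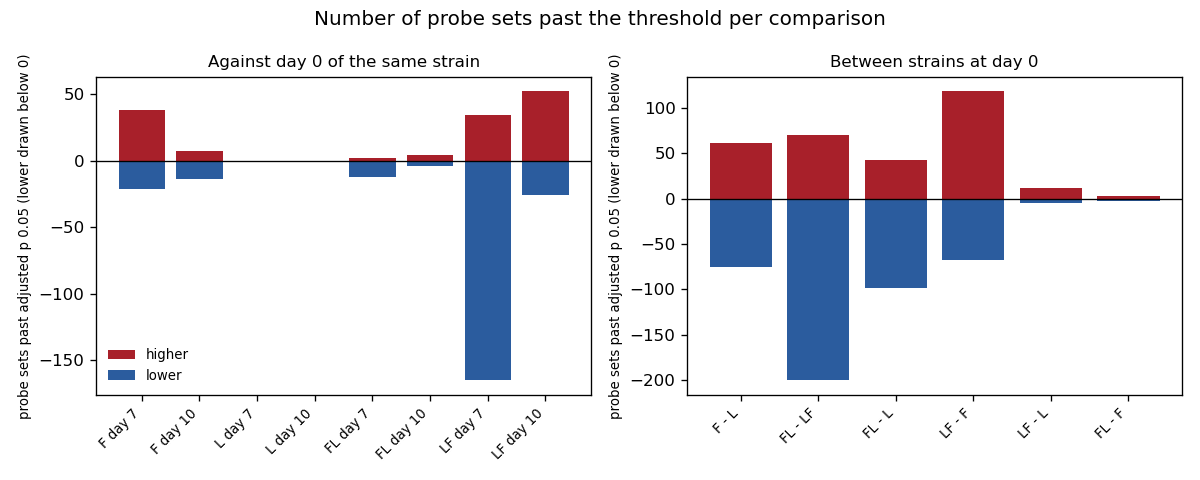
Number of probe sets past an adjusted p of 0.05, drawn above 0 for higher signal and under 0 for lower signal, for each strain against its own day 0 (left) and for strain pairs at day 0 (right). LF at day 7 has the most calls of the 8 comparisons with day 0 (199), and FL against F the fewest between strains at day 0 (6).

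In the day 0 kidneys, the probe sets that differed between strains were fewest between FL and F (6) and between LF and L (17). Differences between strains are differences in array signal. Sequence variants under the probes were not checked for any gene, and stay open as a source of them. Between F and L, Ace was 1.60 ± 0.16 higher in F (adjusted p = 1.83e-09; group means 7.62 ± 0.085 and 6.02 ± 0.21, SD, n = 4), and Agt and Lcn2 were lower in F (-0.92 ± 0.14 and -1.34 ± 0.20, adjusted p = 3.78e-05 and 2.93e-05). All 4 F arrays lay above all 4 L arrays for Ace. The largest differences among named genes were RT1-CE16 (3.26 ± 0.25), Akr1c2 (3.02 ± 0.25), Akr1b8 (2.19 ± 0.47), Gp2 (1.88 ± 0.26) and Tspan1 (1.70 ± 0.19) higher in F, and Ces1e (-2.75 ± 0.22), Acsm5 (-2.40 ± 0.11), Hba-a3 (-2.17 ± 0.33), Cyp2c11 (-1.64 ± 0.43) and Cyp2d2 (-1.47 ± 0.17) lower in F, each at an adjusted p of at most 0.0356. Probe set 7220176, with several symbols (Or2n1e and Or2n1el1), lay further below, at -4.83 ± 0.45. RT1-CE16 is a class I histocompatibility gene, Akr1c2 and Akr1b8 are aldo-keto reductases, and Cyp2c11 and Cyp2d2 are cytochromes P450. Cyp1a1, Havcr1 and Agtr1a differed by 0.31 ± 0.43, -0.11 ± 0.54 and -0.12 ± 0.20, none past the threshold (adjusted p = 0.988, 0.997 and 0.997). Of the histocompatibility genes, 1 of 19 measured members were higher and 0 lower (3 and 0 adjusted over the list alone) in F, the higher one RT1-CE16. As a set it had adjusted p = 2.08e-06, and adjusted p = 0.235 with an estimated correlation. Of the cholesterol synthesis genes, 2 of 14 measured members were higher and 0 lower (4 and 1 adjusted over the list alone) in F, with Hsd17b7 (0.41 ± 0.088) and Insig1 (0.65 ± 0.17). By camera this was adjusted p = 6.80e-05, and adjusted p = 0.579 with an estimated correlation. F and L differed in 61 probe sets higher and 75 lower in F, and in 144 higher and 145 lower after a second quantile normalization. On the arrays of the comparison alone the count was lower by over 1.5 times. So were those of FL against F, FL against L and LF against L, as listed with the processing.

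Between FL and LF, among named genes, Akr1c2 (3.35 ± 0.25), RT1-CE16 (2.88 ± 0.25), Gp2 (2.07 ± 0.26), Tspan1 (1.48 ± 0.19) and Bmal1 (1.39 ± 0.29) were highest over LF, and Ces1e (-3.44 ± 0.22), Or10d5j (-2.95 ± 0.35), Acsm5 (-2.57 ± 0.11), Or2n1 (-2.55 ± 0.75) and Cyp2c11 (-2.04 ± 0.43) furthest under it. Probe set 7220176, with several symbols, lay further under LF, at -5.41 ± 0.45. Of the probe sets higher in F than L, 29 were also higher in FL than LF, and of those lower, 44 were also lower, where independent lists would share 0.485 and 1.71. These comparisons share no arrays. Ace was lower in FL than LF, at -0.90 ± 0.16 (adjusted p = 0.000207), the opposite direction to F and L. Interferon genes Mx1 and Ifitm3 were lower in FL than LF (-1.25 ± 0.31 and -0.70 ± 0.19), where in the list 0 of 21 measured members were higher and 2 lower (0 and 8 adjusted over the list alone). For the whole list camera gave adjusted p = 4.85e-05, and adjusted p = 0.924 with an estimated correlation. Of the macrophage markers, 1 of 28 measured members were higher and 6 lower (1 and 16 adjusted over the list alone), with Clec4a3 (-1.12 ± 0.26), Cd53 (-0.65 ± 0.16) and Fcgr3a (-1.09 ± 0.27) lower and Lilrb4 (1.35 ± 0.25) higher. Tested together the members had adjusted p = 4.85e-05, and adjusted p = 0.924 with an estimated correlation. FL and LF differed in 70 probe sets higher and 200 lower in FL, 101 higher and 443 lower with the block, 279 higher and 246 lower after a second quantile normalization and 197 higher and 239 lower with array medians subtracted. Ifitm3 lost its call after a second quantile normalization (adjusted p = 0.0682) and Or2n1 with the array spread as covariate (0.0612). Without LF day 0 replicate 2, LF day 0 replicate 1 or FL day 0 replicate 2 the totals were 151, 161 and 173.

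FL differed from F in 6 probe sets and LF from L in 17. In FL, Ace was lower than in F at -1.35 ± 0.16 (adjusted p = 1.55e-06). Pitpnm1 and Cyb5b were also lower (-0.93 ± 0.15 and -0.77 ± 0.15), and Asns (1.08 ± 0.18), Nupr1 (1.03 ± 0.21) and Atf5 (0.67 ± 0.12), genes induced by the transcription factor Atf4, were higher, each at an adjusted p of at most 0.0245. The falls of Asns, Nupr1 and Atf5 under treatment in FL rest on the same FL day 0 arrays, so they are not independent of these differences. In LF, Ace was 1.15 ± 0.16 higher than in L (adjusted p = 3.36e-05), together with Krt19 (1.43 ± 0.28), Dbp (1.41 ± 0.20), Or51q1 (1.38 ± 0.27) and Bhlhe41 (1.03 ± 0.19), while Bmal1 (-1.69 ± 0.29), Rtcb (-1.09 ± 0.22), Grik2 (-1.07 ± 0.20), Cacng5 (-1.06 ± 0.22) and Ndrg1 (-0.80 ± 0.093) were lower. Dbp, Bhlhe41 and Bmal1 belong to the daily clock. With the block 5 higher and 6 lower probe sets passed between FL and F and 21 higher and 9 lower between LF and L. A second quantile normalization gave 24 higher and 20 lower between LF and L.

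Across the pairs, FL differed from L in 42 probe sets higher and 98 lower, and LF from F in 118 higher and 68 lower. Among named genes, Akr1c2 (3.39 ± 0.25), RT1-CE16 (2.99 ± 0.25), Gp2 (2.11 ± 0.26), Tspan1 (1.55 ± 0.19) and Lilrb4 (1.30 ± 0.25) were highest in FL over L, and Ces1e (-2.90 ± 0.22), Acsm5 (-2.63 ± 0.11), Hba-a3 (-2.16 ± 0.33), Or10d5j (-2.04 ± 0.35) and Cyp2c11 (-1.67 ± 0.43) lowest. Likewise Ces1e (3.29 ± 0.22), Or2n1 (3.04 ± 0.75), Acsm5 (2.33 ± 0.11), Or10d5j (2.08 ± 0.35) and Hba-a3 (2.02 ± 0.33) were highest in LF over F, and RT1-CE16 (-3.15 ± 0.25), Akr1c2 (-2.98 ± 0.25), Akr1b8 (-2.40 ± 0.47), Akr1b10 (-1.86 ± 0.41) and Gp2 (-1.84 ± 0.26) lowest. Probe set 7220176, with several symbols, lay beyond these genes at -4.915 ± 0.45 for FL against L and 5.325 ± 0.45 for LF against F. Ace did not pass the threshold in either comparison, at 0.25 ± 0.16 for FL against L (adjusted p = 0.656) and -0.45 ± 0.16 for LF against F (adjusted p = 0.176). For LF against F it passed after a second quantile normalization (adjusted p = 0.00294), with array medians subtracted (0.0108), with array weights (0.0292) and with the array spread as covariate (0.00137), and for FL against L with that covariate (0.0399). Agt and Lcn2 were higher in LF than F (0.79 ± 0.14 and 1.12 ± 0.20, adjusted p = 0.000361 and 0.000389). Of the histocompatibility genes, 0 of 19 measured members were higher and 4 lower (0 and 8 adjusted over the list alone) in LF than F, namely RT1-CE16, Cd74 (-0.58 ± 0.13), RT1-DMa (-0.51 ± 0.12) and RT1-Db1 (-0.47 ± 0.13). Camera on the list gave adjusted p = 2.20e-06, and adjusted p = 0.238 with an estimated correlation. With the block the counts were 61 higher and 173 lower for FL against L and 202 higher and 99 lower for LF against F, and after a second quantile normalization 151 higher and 143 lower and 191 higher and 200 lower. With array medians subtracted they were 129 higher and 120 lower and 181 higher and 166 lower. Without L day 0 replicate 4 the FL against L total was 216, and without LF day 0 replicate 2 that of LF against F was 113.

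Whether the strains responded differently was tested on the difference between their changes from day 0. Lcn2 separated LF from the other 3 strains at day 10. Its rise in LF exceeded the value in L by 1.78 ± 0.29 and that in F by 1.75 ± 0.29 (adjusted p = 0.00256 and 0.00348), and FL minus LF was -2.29 ± 0.29 (adjusted p = 1.02e-05). Ces1e, a carboxylesterase, stood at -1.80 ± 0.31 for LF minus L (adjusted p = 0.00317), and Acaa2, a mitochondrial enzyme of fatty acid oxidation, at -0.94 ± 0.19 for LF minus F (adjusted p = 0.0464). With each replicate number left out in turn, Lcn2 kept its call in 4 of 4 cases for FL minus LF, 2 for LF minus L and 0 for LF minus F (adjusted p = 0.0531 to 0.0893), Ces1e in 1 and Acaa2 in 0 (adjusted p = 0.0795 to 0.944). Havcr1, LF minus L, was 2.85 ± 0.77 with a 95% interval of 1.30 to 4.40 that excludes 0 for the single gene, and missed the threshold over all probe sets (adjusted p = 0.369). For Cyp1a1, LF minus F was -2.44 ± 0.61 (interval -3.69 to -1.20, adjusted p = 0.237). Of the injury markers, 1 of 22 measured members were higher and 0 lower (10 and 0 adjusted over the list alone) in the response of LF than of L. The set test gave adjusted p = 8.38e-19, and adjusted p = 0.0295 with an estimated correlation.

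The counts of probe sets with different responses were small. By limma, 1 probe set passed for FL against LF, 2 for LF against F and 2 for LF against L, and 5, 7 and 8 with the block. A second quantile normalization gave 5 higher and 3 lower for FL against LF and 5 higher and 8 lower for LF against F, and subtraction of array medians 4 higher and 2 lower and 2 higher and 7 lower, beside 0 higher and 1 lower and 1 higher and 1 lower. None passed for F against L at day 7 or day 10, FL against F or FL against L, where 300, 522, 422 and 218 probe sets had an unadjusted p under 0.05. Of these only 522 lies above 0.05 of the 8797 probe sets, the share expected with no change. The block gave 0 for F against L at day 7 and 0 at day 10. Havcr1 for F against L was 3.15 ± 0.77 at day 7 (interval 1.59 to 4.70, adjusted p = 0.218) and 1.40 ± 0.77 at day 10 (interval -0.15 to 2.95, adjusted p = 0.783).

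The moderated F test over all strain by time terms called 17 probe sets (36 with the block, and 0 to 9 without a replicate number), against 548 at an unadjusted p under 0.05. The 10 genes with the smallest p were Lcn2 (adjusted p = 0.000422), Ndrg1 (0.000422), Per2 (0.00273), Mx2 (0.00987), Sik1 (0.0102), Ptprq (0.0127), Slfn4 (0.0143), Per3 (0.0185), Dbp (0.0185) and Asns (0.0185). Per2, Per3 and Dbp are clock genes, and in LF the log2 change of Dbp was -1.76 at day 7 and -1.43 at day 10, beside -0.065 and -0.34 in L. Mx2 in LF stood at -2.04 at day 7 and 0.69 at day 10, beside -0.91 and -0.86 in F. Asns stood at -1.19 and -0.83 in FL and at 0.23 and 0.16 in F. At day 0 Asns was higher in FL than F, and that difference rests on the same FL day 0 arrays as the falls. Ndrg1, a stress-responsive gene, stood at 1.01 and 0.66 in LF, and at 0.022 and 0.035 in L. At day 0 Ndrg1 was lower in LF than L (-0.80), on the same LF day 0 arrays.

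**Figure D3:**
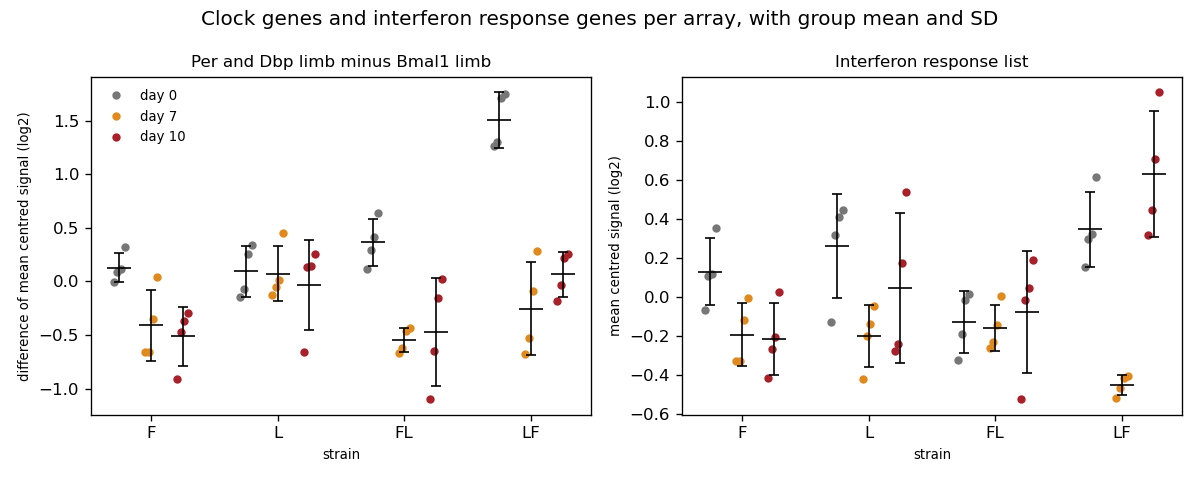
Clock gene difference (left) and mean of the interferon response list (right) per array, log2 signal centred on each gene's mean, by strain and day, with the group mean ± SD of 4 arrays. The left axis is the mean of 8 genes of the Per and Dbp limb minus the mean of 4 genes of the Bmal1 limb, and the LF day 0 arrays lie between 1.26 and 1.75, above all other arrays.

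The other lists at day 10 in the mean of the strains had these counts of rises and falls. Rises and falls numbered 2 and 0 of 15 AhR and Nrf2 targets (camera adjusted p = 0.0613), 2 and 1 of 21 matrix and fibrosis genes (camera adjusted p = 0.106) and 1 and 4 of 27 chemokine, cytokine and adhesion genes (camera adjusted p = 0.177). The counts were 4 and 0 of 21 complement and coagulation genes (camera adjusted p = 0.0696), 0 and 0 of 19 histocompatibility genes (camera adjusted p = 0.726) and 0 and 1 of 13 cell cycle genes (camera adjusted p = 0.921). They were 0 and 0 of 14 cholesterol synthesis genes (camera adjusted p = 0.622), 1 and 0 of 18 hypoxia response genes (camera adjusted p = 0.921) and 0 and 0 of 24 vasoactive and natriuretic genes (camera adjusted p = 0.0696). Counts stood at 0 and 1 of 30 proximal tubule markers (camera adjusted p = 0.714), 0 and 0 of 10 podocyte markers (camera adjusted p = 0.726) and 0 and 0 of 12 endothelium markers (camera adjusted p = 0.106). These were 2 and 0 of 28 macrophage and monocyte markers (camera adjusted p = 0.726), 0 and 1 of 18 T and natural killer cell markers (camera adjusted p = 0.128) and 0 and 0 of 5 B and plasma cell markers (camera adjusted p = 0.622). The last counts were 2 and 0 of 13 granulocyte and mast cell markers (camera adjusted p = 0.0355), 0 and 0 of 7 erythroid cell and platelet markers (camera adjusted p = 0.383) and 0 and 0 of 13 adipose and adrenal genes (camera adjusted p = 0.921). The granulocyte and mast cell list lost its call with an estimated correlation (adjusted p = 0.161) and with the block (adjusted p = 0.0583). The angiotensin and kallikrein list had 1 fall, Ace, among 13 members. As a set it had adjusted p = 0.00168, and adjusted p = 0.176 with an estimated correlation.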

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

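The tests of the hour of collection, of the array run, of the array spread, of LF at every day and of white blood cells were chosen only after the data were seen, while the splits of the samples were set beforehand. Lcn2 responded differently between strains at day 10 by a direct test of the difference in log2 change, at -2.29 for FL minus LF, 1.75 for LF minus F and 1.78 for LF minus L. For Acaa2 the difference was -0.94 (LF minus F), and for Ces1e -1.80 (LF minus L). With a replicate number left out, Lcn2 for LF minus F kept its call in 0 of 4 cases, with adjusted p of 0.0531 to 0.0893, and for LF minus L in 2 of 4 (limma). The F test of any strain difference in response put Lcn2 at an adjusted p of 0.000422, Ndrg1 at 0.000422, Per2 at 0.00273, Mx2 at 0.00987, Sik1 at 0.0102, Ptprq at 0.0127, Slfn4 at 0.0143, Per3 at 0.0185, Dbp at 0.0185 and Asns at 0.0185 (limma).

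Some arrays lay far from the other 3 of their group by Dixon's ratio, which was tested in 156 groups and passed in 10, where chance gives about 1 in 20 (7.8). Cyp1a1 was at 5.70 in FL day 10 replicate 4, and Havcr1 at 4.32 in L day 0 replicate 3. Hmox1 was at 5.74 in F day 10 replicate 4 and at 5.22 in LF day 10 replicate 3. Mx2 was at 5.34 in F day 7 replicate 1, where probe set 7105149 without a gene name was at 5.12. Clu was at 8.77 in FL day 7 replicate 1 and at 8.56 in L day 0 replicate 4, and Timp1 at 5.41 in F day 0 replicate 4. The array spread was 2.47 in F day 0 replicate 2.

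Clock genes stood apart in LF at day 0. The mean of the Per and Dbp limb minus that of the Bmal1 limb was 1.31 log2 higher in LF than in the other strains (95% interval 0.95 to 1.67), with LF arrays between 1.26 and 1.75 and other arrays at most at 0.639, and 0.63 higher (0.44 to 0.82) without the genes that had brought the pattern up, on the same arrays. A shift of whole runs was excluded by the design, since each run held 1 array of every group (the LF array was highest in 4 of 4 runs, which the ranges already implied), and array spread was argued against, since 106% of the difference was left with the spread as covariate. LF over days 7 and 10 differed by 0.22 (-0.03 to 0.47), too little for a strain effect of that size that lasts under treatment. All rats of days 7 and 10 were treated, so a strain difference in untreated LF kidneys stays open. A different hour of collection of the LF day 0 kidneys may account for the pattern, and part of the LF changes in Dbp, Per2, Per3 and Bmal1 with it, as the limbs moved oppositely (0.79 and -0.52). The labels state a light and dark cycle but not the hour, and a shift of the clock by treatment stays open, since the limb difference also stood lower than day 0 in F (-0.54, -0.98 to -0.099, at day 7 and -0.64, -1.08 to -0.20, at day 10) and in FL (-0.91, -1.35 to -0.47, and -0.84, -1.28 to -0.40), while the intervals in L included 0 (-0.021, -0.46 to 0.42, and -0.12, -0.56 to 0.31).

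Interferon response genes were low in LF at day 7. The list mean stood at -0.80 relative to day 0 (-1.12 to -0.47), beside -0.46 (-0.79 to -0.14) in L, -0.32 (-0.65 to 6.01e-05) in F and -0.031 (-0.35 to 0.29) in FL, and LF minus the mean of these 3 was -0.53 (-0.90 to -0.15), while day 10 lay 1.08 above day 7. A shift of whole runs was excluded by the design, as above (LF day 7 lay below LF day 0 and day 10 in 4 of 4 runs, as already seen in the arrays), and array spread was argued against as the whole cause, since 80.3% of the change was left with the spread as covariate. Fewer white blood cells in the tissue cannot be told apart from a lower response per cell, because the macrophage list stood at -0.33 (-0.55 to -0.096) and the T cell list at -0.12. Strain and treatment day, which the design names, stay open as biological explanations.

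The same arrays were split into groups in other ways, and each count of probe sets was compared with the highest from another split and with the number of splits as large, the real one included. The share of splits as large lay under 0.05 for strain mean day 7 (435 against 1, 1 of 100), strain mean day 10 (212 against 368, 2 of 100), F day 7 (59 against 1, 1 of 35), F day 10 (21 against 1, 1 of 35), L day 10 (1 against 0, 1 of 35), FL day 7 (14 against 3, 1 of 35), LF day 7 (199 against 1, 1 of 35) and LF day 10 (78 against 1, 1 of 35). It also lay under 0.05 for F against L (136 against 0, 1 of 35), FL against LF (270 against 1, 1 of 35), FL against F (6 against 1, 1 of 35), FL against L (140 against 65, 1 of 35), LF against F (186 against 0, 1 of 35), LF against L (17 against 1, 1 of 35), the LF against F response at day 10 (2 against 7, 2 of 100), the LF against L response at day 10 (2 against 1, 1 of 100) and the F test (17 against 11, 1 of 100). These shares were not adjusted over the comparisons, and counts of 1 or 2 probe sets give little to judge by. In the LF against F response another split called 7, and 0 probe sets passed without any one replicate number. The share was 0.05 or more for strain mean day 10 against day 7 (10 against 2527, 5 of 100), L day 7 (1 against 3, 2 of 35), FL day 10 (8 against 216, 4 of 35) and the FL against LF response at day 10 (1 against 1, 5 of 100). The 1 call in L at day 7 was probe set 7105149 (limma adjusted p = 2.93e-08), which fell in every strain at both days. A count of 1 cannot speak for or against it. Likewise Lcn2 in the FL against LF response kept its call without each replicate number in turn. Nothing passed in the real split for the F against L response at day 7 (0 against 1, 100 of 100), the F against L response at day 10 (0 against 1, 100 of 100), the FL against F response at day 10 (0 against 756, 100 of 100) and the FL against L response at day 10 (0 against 79, 100 of 100). Splits with several times the real count in the strain mean of day 10 against day 7, FL day 10 and the LF against F response, and those with 756 and 79 where the real FL against F and FL against L responses gave 0, point to a structure among the samples other than the groups. For strain mean day 10 another split also gave more than the real one. Among the 8 of 35 splits that part all 4 runs as the real one does, the real split had the highest count in each of the 14 comparisons of 2 groups, and the other splits put arrays of the same run on the same side.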

How the results depend on the processing

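The array spread covariate, the omission of the 5 arrays of lowest spread and single arrays left out of the strain mean contrasts were chosen only after results were seen. Of 382 values of named genes and leading list members past the threshold, 380 stayed past it in the same direction with the block, 367 after a second quantile normalization, 366 with array medians subtracted, 378 with array weights, 357 with the spread covariate, 382 with the trended robust variance and 333 without the 5 arrays of lowest spread. Without the dimmest 0.25 of probe sets 357 of the 357 left stayed past it. With replicate number 1, 2, 3 or 4 left out 232, 164, 200 and 281 stayed past it, all values in the same direction, on fewer arrays. The calls that ended with the block were those of Cyp1a1 and Tagln in FL at day 10, and for the genes named in the results, calls that ended with another scaling, weight, covariate or without the 5 arrays stand beside their values. Of 177 list calls at the preset correlation, 166 held with the block, 177 with the mean over a gene's probe sets, 22 with the directional fry p and 7 with an estimated correlation. The 25 counts stayed within 1.5 times under the trended robust variance.

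Numbers of probe sets past the threshold that moved by over 1.5 times follow by setting, and the cause was not tested except where fewer arrays or fewer probe sets were fitted. With the block the counts were 976 for strain mean day 7, 21 for strain mean day 10 against day 7, 42 for F day 10, 2 for L day 7, 2 for L day 10, 722 for LF day 7, 544 for FL against LF, 11 for FL against F, 234 for FL against L and 301 for LF against F. Under the same setting they were 30 for LF against L, 5 for the FL against LF response at day 10, 7 for the LF against F response at day 10, 8 for the LF against L response at day 10 and 36 for the F test. After a second quantile normalization the counts were 407 for strain mean day 10, 141 for F day 7, 82 for F day 10, 3 for L day 7, 4 for L day 10, 16 for FL day 10, 394 for LF day 7, 146 for LF day 10, 289 for F against L and 525 for FL against LF. Under the same setting they were 10 for FL against F, 294 for FL against L, 391 for LF against F, 44 for LF against L, 8 for the FL against LF response at day 10, 13 for the LF against F response at day 10, 9 for the LF against L response at day 10 and 29 for the F test. With array medians subtracted the counts were 357 for strain mean day 10, 102 for F day 7, 62 for F day 10, 3 for L day 7, 5 for L day 10, 23 for FL day 7, 307 for LF day 7, 150 for LF day 10, 248 for F against L and 436 for FL against LF. Under the same setting they were 10 for FL against F, 249 for FL against L, 347 for LF against F, 36 for LF against L, 6 for the FL against LF response at day 10, 9 for the LF against F response at day 10, 9 for the LF against L response at day 10 and 32 for the F test. With array weights the counts were 1128 for strain mean day 7, 50 for strain mean day 10 against day 7, 149 for F day 7, 67 for F day 10, 16 for L day 7, 4 for L day 10, 332 for LF day 7, 164 for LF day 10, 342 for F against L and 561 for FL against LF. Under the same setting they were 15 for FL against F, 406 for FL against L, 374 for LF against F, 36 for LF against L, 1 for the F against L response at day 10, 9 for the FL against LF response at day 10, 1 for the FL against F response at day 10, 8 for the LF against F response at day 10, 9 for the LF against L response at day 10 and 45 for the F test. With the array spread as covariate the counts were 508 for strain mean day 10, 5 for strain mean day 10 against day 7, 183 for F day 7, 79 for F day 10, 3 for L day 7, 6 for L day 10, 25 for FL day 7, 18 for FL day 10, 217 for LF day 10 and 351 for F against L. Under the same setting they were 513 for FL against LF, 326 for FL against L, 466 for LF against F, 58 for LF against L, 8 for the FL against LF response at day 10, 20 for the LF against F response at day 10, 19 for the LF against L response at day 10 and 43 for the F test. On the arrays of the comparison alone the counts were 11 for F day 10, 3 for FL day 7, 2 for FL day 10, 59 for LF day 7, 49 for LF day 10, 79 for F against L, 1 for FL against F, 64 for FL against L, 8 for LF against L and 3 for the F against L response at day 7. Without the 5 arrays of lowest spread the counts were 8 for F day 10, 125 for LF day 7, 418 for FL against LF, 5 for the FL against LF response at day 10, 5 for the LF against F response at day 10 and 10 for the F test. Without the dimmest 0.25 of probe sets the counts were 4 for the LF against F response at day 10 and 5 for the LF against L response at day 10.

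Leaving out single arrays or all arrays of a replicate number gave these lowest and highest counts, where the F test was run only without whole replicate numbers. Ranges were 99 to 720 for strain mean day 7, 91 to 245 for strain mean day 10, 0 to 64 for strain mean day 10 against day 7, 7 to 52 for F day 7, 4 to 27 for F day 10, 1 to 4 for L day 7, 1 to 2 for L day 10, 5 to 16 for FL day 7 and 1 to 8 for FL day 10. Further ranges were 27 to 430 for LF day 7, 25 to 79 for LF day 10, 57 to 139 for F against L, 80 to 427 for FL against LF, 2 to 8 for FL against F, 58 to 228 for FL against L, 77 to 186 for LF against F, 6 to 19 for LF against L and 0 to 0 for the F against L response at day 7. The last ranges were 0 to 1 for the F against L response at day 10, 1 to 8 for the FL against LF response at day 10, 0 to 2 for the FL against F response at day 10, 0 to 2 for the FL against L response at day 10, 0 to 4 for the LF against F response at day 10, 0 to 4 for the LF against L response at day 10 and 0 to 9 for the F test.

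Single arrays that moved a count by over 1.5 times are named here by group and replicate. For strain mean day 7 the count was 284 without LF day 0 replicate 2, 720 without L day 0 replicate 4 and 289 without F day 7 replicate 4. For strain mean day 10 against day 7 the count was 64 without FL day 10 replicate 4, 17 without LF day 10 replicate 2, 6 without LF day 10 replicate 4 or F day 10 replicate 1 or FL day 7 replicate 3 or F day 7 replicate 2 or L day 7 replicate 2 or L day 7 replicate 4, 4 without F day 10 replicate 2 or FL day 7 replicate 4 or F day 7 replicate 3, 16 without F day 10 replicate 4 and 5 without L day 10 replicate 3 or LF day 7 replicate 3. For F day 7 the count was 37 without F day 0 replicate 4. For F day 10 the count was 12 without F day 0 replicate 1, 11 without F day 0 replicate 3, 7 without F day 0 replicate 4, 13 without F day 10 replicate 3 and 8 without F day 10 replicate 4. For L day 7 the count was 3 without L day 0 replicate 4. For FL day 7 the count was 9 without FL day 0 replicate 1. For FL day 10 the count was 3 without FL day 0 replicate 1, 1 without FL day 0 replicate 2 or FL day 0 replicate 3, 4 without FL day 0 replicate 4, 5 without FL day 10 replicate 2 and 2 without FL day 10 replicate 3. For LF day 7 the count was 91 without LF day 0 replicate 1, 57 without LF day 0 replicate 2, 131 without LF day 7 replicate 2 and 84 without LF day 7 replicate 3. For LF day 10 the count was 51 without LF day 0 replicate 1 and 47 without LF day 10 replicate 1. For FL against LF the count was 173 without FL day 0 replicate 2, 161 without LF day 0 replicate 1 and 151 without LF day 0 replicate 2. For FL against L the count was 216 without L day 0 replicate 4. For LF against F the count was 113 without LF day 0 replicate 2. For the FL against LF response at day 10 the count was 3 without FL day 0 replicate 4 and 5 without FL day 10 replicate 4. For the FL against F response at day 10 the count was 2 without FL day 0 replicate 4. For the FL against L response at day 10 the count was 2 without FL day 0 replicate 4. For the LF against F response at day 10 the count was 1 without LF day 0 replicate 1 or F day 0 replicate 3 or F day 0 replicate 4 or LF day 10 replicate 3 or LF day 10 replicate 4 or F day 10 replicate 3 and 4 without F day 10 replicate 4. For the LF against L response at day 10 the count was 4 without LF day 10 replicate 3 or L day 10 replicate 4.

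No value that changed sign was past the threshold in either setting. Lcn2 in L at day 7 was 0.014 after a second quantile normalization and 0.005 with array medians subtracted. Agt in the strain mean was -0.0039 at day 7 with array weights and 0.012 at day 10 without the 5 arrays of lowest spread. Lcn2 in the F against L response at day 10 was -0.027 without those arrays. With replicate numbers left out, sign changes occurred in the ranges -0.02 to 0.034 for Agt at day 7 in the strain mean, -0.19 to 0.037 for Lcn2 and -0.087 to 0.14 for Havcr1 in L at day 7, -0.23 to 0.083 for Havcr1 in F against L at day 0, and -0.18 to 0.23 for Lcn2 in the F against L response at day 10. The cause was not tested. The depth of an array is its signal over background, which the deposited values do not hold, so a gene near the lower end of the range is limited by background to an unknown extent.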

Other observations

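The tests of Ace and its neighbours, and the contrasts over all days, were chosen only after the results were seen. With days 0, 7 and 10 pooled, FL differed from F in 31 probe sets (8 higher and 23 lower) and LF from L in 61 (37 higher and 24 lower), against 644 between F and L. Genes past the threshold in both were Ace, Cacng5, Ehhadh, Clu and Gpnmb, 5 in number where independent lists would share 0.215. For 4 of them the directions were opposite. Ace stood at -1.06 ± 0.091 in FL minus F and 0.89 ± 0.091 in LF minus L, and Cacng5, a calcium channel subunit, at 0.77 ± 0.13 and -0.56 ± 0.13. Clu stood at -0.59 and 0.63 and Gpnmb, a marker of injured tubule and of macrophages, at -0.52 and 0.46. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was lower in both (-0.36 and -0.32). These contrasts mix carrier and treated days. Clu on LF day 0 arrays (8.46 to 8.85) was not above L day 0 (8.56 to 8.89). At day 10 LF (10.09 to 10.85) lay above L (8.72 to 9.75). Clu in FL at day 0 (7.93 to 8.27) lay below F (8.41 to 8.61). Gpnmb in FL at day 0 stood at -0.595 against L and -0.6225 against LF, so LF and L were close. The pooled LF minus L values of Clu and Gpnmb thus reflect treated days. Cacng5 was past the threshold between LF and L at day 0 but not between FL and F at day 0. It fell in F at day 10, which enters its pooled FL minus F value.

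A candidate explanation for Ace is a chromosome segment around it that differs between FL and F and between LF and L. Among the 100 measured genes nearest to Ace, 3 were past the threshold between LF and L (Rnd2, Acbd4 and Cacng5), against 53 of the other 7479 genes (one-sided Fisher exact p = 0.0373), and 16 of 635 genes on the same chromosome against 40 of 6944 elsewhere. Cacng5 was already among the calls between LF and L at day 0 when this test was chosen, so the p partly restates that result. Between FL and F it was 1 of 100, Cacng5 (one-sided Fisher exact p = 0.311), and 3 of 635 on the chromosome against 25 of 6944 elsewhere, which leaves that pair open because so few genes were past the threshold. Cacng5 was not past the threshold between FL and F at day 0, so that 1 neighbour may rest on treated days. Between F and L the neighbours did not stand out, with 7 of 100 against 580 of 7479 (one-sided Fisher exact p = 0.665). The array spread was argued against, since with it as a covariate the larger adjusted p of Ace in both pairs was 1.84e-13 (limma). Sequence variants under the Ace probes stay open, as probe-level values were not analysed here.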
